A study of Paracentrotus lividus with 19 samples.

How the data were processed

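The series holds poly(A) RNA sequencing of embryos of the sea urchin Paracentrotus lividus. Per the labels' protocols, fertilized eggs were left unexposed or were exposed for 24 h to Fe2O3 particles, to ZnO particles, or to the salts FeCl3 and ZnSO4 at equivalent metal concentrations, and the embryos were then harvested for RNA. The labels give 5e-05 M and 4 mg per L of iron for Fe2O3, and 1e-05 M and 0.8 mg per L of zinc for ZnO. These molar and mass figures were not reconciled and are given as the labels state them. The 19 libraries comprised 4 unexposed controls, 4 Fe2O3, 4 FeCl3, 3 ZnO and 4 ZnSO4 libraries. Titles place each library in a set named F1, F2 or F3, with 2 libraries per treatment in F1 (1 for ZnO) and 1 per treatment in F2 and in F3. The labels do not say what the sets are, nor that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

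The authors deposited a single table of counts, 63389 features by 19 libraries, and its values were whole numbers without normalization. Trim Galore 0.4.0, BWA 0.7.12-r1039 and SAMtools 1.3.1 are named per the submitters' processing notes, without their roles. The reference assembly, the counting program, its strand setting and its treatment of reads that match several features are not given in the sources used here. Such a step could divide the reads of near-identical features, which concerns the 23 features named MT (metallothionein) above all. Their individual values are therefore uncertain, and the sum of their counts was tested as well. Of the features, 51360 were numbered contigs, 11343 carried a LOC identifier, 110 carried another kind of locus tag and 576 carried a gene name (391 different names). A suffix, as in MT.2.23, numbers the contig and gives the contigs of that name. No reference genome was used, and the files do not pair LOC identifiers or numbered contigs with gene names.

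Library totals ran from 24438369 to 32801015 counts, and every row named a feature. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Features were filtered with filterByExpr on treatment, which left 62865 features, and libraries were scaled by TMM. One quasi-likelihood model with terms for set and treatment was fitted to all 19 libraries, with 12 residual degrees of freedom, 11.1 prior degrees of freedom and a common dispersion of 0.015. A feature was called at an adjusted p under 0.05 (Benjamini-Hochberg over all features tested in a contrast). The contrasts were each treatment against control, each particle against its salt, the mean of both zinc treatments against the mean of both iron treatments, and the sets against each other. Log2 fold changes are given with their standard errors, and CPM (counts scaled to library size) with the SD over the libraries of a treatment. Differences of a treatment effect between sets were tested with set-by-treatment terms, whose residual spread comes from the F1 pairs alone (4 degrees of freedom).

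Gene lists were fixed before the data were examined: metallothionein and zinc transport, iron homeostasis, heat shock and chaperones, antioxidant and glutathione, xenobiotic transport and metabolism, skeleton, pigment and immune cells, endoderm and gut, ectoderm patterning, apical plate and neurons, cilia, cell cycle, apoptosis and DNA damage, matrix and secreted proteases, ribosomal proteins, oxidative phosphorylation, early blastula stage, late stage, and muscle. Further spellings of the same genes were added once the feature names had been seen and before any contrast was run. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a contrast. camera compares a list with the other features. fry tests whether the members move, on balance, one way, and its mixed version whether they change in either direction. Medians of a list come from the edgeR fit to all libraries, and under other settings from limma on log2 CPM. List p-values are those of camera at the preset correlation unless another is named.

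The rule for named genes was also set before the data were examined. Per treatment against control and per particle against salt, it takes up to 12 features higher and 12 lower with the largest log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM (prior count 2) of at least 1, the same sign in F1, F2 and F3, and a gene name, with 1 feature per name. It adds the measured members of the metallothionein and iron lists, and up to 4 members with the smallest p from each other list. Members of lists named for the zinc against iron contrast, which the rule does not cover, were chosen after their values were seen. A feature that the rule takes is not reported here.

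The alternatives tried were RLE size factors, the DESeq2 1.42.0 Wald test, no filter, a stricter filter (CPM of 2 in 4 libraries) and no set term. Others were the replicate number as a block, the F1 libraries of each treatment summed and a fit to only the groups compared. Each set and each library was also left out. Called features with an estimated log2 fold change above 1 in size were counted too, with no test against that bound. Counts summed over features of 1 name were added as an alternative after the data were seen. Replicate agreement was checked by correlation of log2 CPM and by a chi-square test of counts over features with a summed count of at least 10. Comparisons that share the controls were set beside 100 simulated data sets without treatment effects and beside values from split controls (F1 replicate 1 and F2 controls for one comparison, F1 replicate 2 and F3 controls for the other). A share of zinc-library reads in other libraries was set from the metallothionein features, either all 23 or the 5 called with FeCl3. The change it predicts was then set beside the observed one for other features, chosen with one zinc treatment and sized with the other, with each part of the controls. This makes 8 settings for each size of zinc effect. A pooled test instead chose and sized the features that rose by over 1 by the same mean of both zinc treatments. Intervals of medians came from 1000 bootstrap draws at 95%. Counts were also refitted with the libraries regrouped, over all splits or 100 drawn, and within sets or treatments.

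The tests were checked on simulated counts for all 62865 features, with 200 features changed. For Fe2O3 against control, 35.8% of 1.5-fold, 62.7% of 2-fold and 92.4% of 4-fold changes were recovered, and 10 of 137 calls were false. For ZnO against control, the shares were 32.8%, 68.7% and 95.5%, and 8 of 139 calls were false.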

Results

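Transcript counts were compared in whole embryos of the sea urchin Paracentrotus lividus harvested 24 h after fertilization, across unexposed controls (4 libraries) and embryos exposed to Fe2O3 particles (4), FeCl3 (4), ZnO particles (3) or ZnSO4 (4). The design asks which transcripts respond to each metal, and whether a particle differs from a salt that carries the same metal. Each library held 24438369 to 32801015 counts, and 56380 of the features had at least 1 count in all 19 libraries. The median feature had a total of 1808 counts over the 19 libraries. Counting error as well as the spread between libraries therefore limits the precision for many features.

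Differences between the sets F1, F2 and F3 exceeded those between treatments by far. Log2 CPM correlated at 0.982 to 0.983 within the 4 pairs of the same set and treatment, at 0.968 to 0.984 between treatments of a set, and at 0.808 to 0.839 between sets. Of the 62865 features tested, 44327 (70.5%) differed between F2 and F1, 43658 (69.4%) between F3 and F1, and 40359 (64.2%) between F3 and F2. The first 2 principal components, with 52.2% and 32.3% of the variance, separated the sets, so the set entered every test of a treatment. The pairs of the same set and treatment differed by more than sampling noise (chi-square per degree of freedom 4.16 to 7.93), and all libraries were kept as separate samples. With set means removed, the first component (19.6% of the variance) placed the 7 zinc libraries between 15.2 and 72.7 and the 12 control and iron libraries between -36.8 and -14.3. The next component (9.79%) placed the F1 ZnSO4 libraries at -39.8 and -49.4 and the other zinc libraries, of ZnO in every set and of ZnSO4 in F2 and F3, between 20.9 and 38.3.

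**Figure D1:**
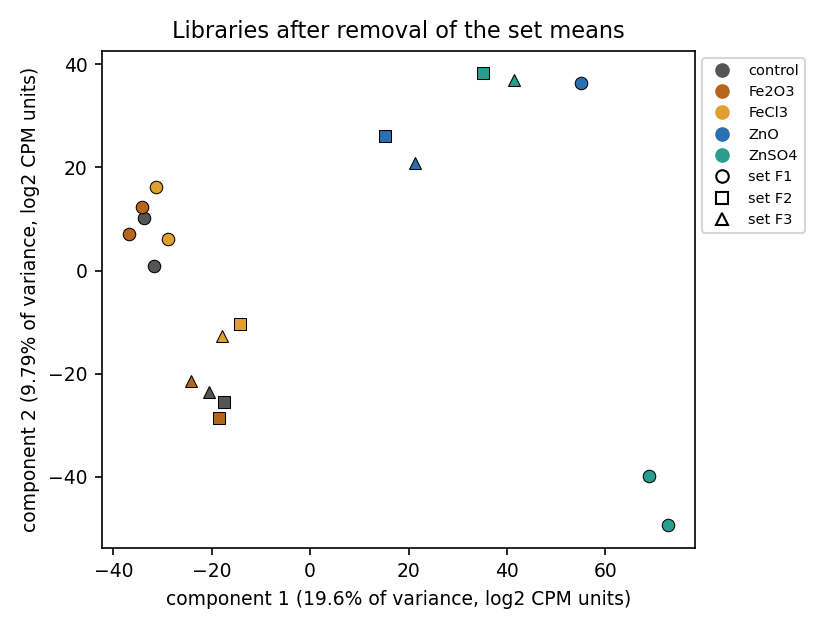
Principal components 1 and 2 of log2 CPM after the mean of each set was removed, with 1 point per library, colours for treatments and marker shapes for sets. Zinc libraries lie at 15.2 to 72.7 on component 1, the control and iron libraries at -36.8 to -14.3, and the second component parts the F1 ZnSO4 libraries (-39.8 and -49.4) from the other zinc libraries (20.9 to 38.3).

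In embryos exposed to ZnO particles, all 23 features named for metallothionein, a small protein that binds zinc and other metals, rose. The largest rise was that of MT.19.23, by 4.39 ± 0.22 on the log2 scale (SE, adjusted p = 3.56e-12), and the smallest that of MT.15.23, by 0.71. Summed over the 23 features, metallothionein stood at 5510 ± 1270 CPM in controls (SD, n = 4) and at 10900 ± 2020 CPM with ZnO (n = 3), a log2 rise of 1.00 ± 0.09 (SE, adjusted p = 2.06e-07). Transcripts of MMP16, a membrane-type matrix metalloproteinase, rose by 1.28 ± 0.11 (SE, adjusted p = 1.12e-07), and those of ACTG1, a cytoplasmic actin, rose from 134 ± 31.9 to 288 ± 47.8 CPM (SD, adjusted p = 1.72e-05).

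DLX and NK2.1, homeobox genes that encode transcription factors of embryonic patterning, fell with ZnO, DLX by a log2 change of -1.56 ± 0.33 (SE, adjusted p = 0.00947) and NK2.1 by one of -1.29 ± 0.31 (adjusted p = 0.0269). HMB1 fell from 157 ± 42.1 to 34.7 ± 17.3 CPM (SD, adjusted p = 4.31e-06). Among the other falls, log2 changes were -1.40 ± 0.20 for ACAC.1.3 (acetyl-CoA carboxylase, adjusted p = 0.000222), -0.60 for CPT1B and -0.57 for CPT1A (carnitine palmitoyltransferases, adjusted p = 0.00125 and 0.00136). ARC3 changed by -1.36 and EH2 by -0.86. Smaller rises were those of EGIP (exogastrula-inducing polypeptide, 0.64), the actin features ACT1.1.2 and ACT2 (0.55 and 0.36), the ETS factor gene ERG.1.2 (0.53), NADK.1.3 (NAD kinase, 0.42), the astacin protease gene BMP1 (0.41) and DUOX1.1.2 (dual oxidase, 0.38), and FREM2, an extracellular matrix gene, fell by 0.59.

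By list, 23 of the 24 members of the metallothionein and zinc transport list rose with ZnO (23 higher and 1 lower adjusted over the list alone, median log2 change 1.01, adjusted p = 5.49e-57, adjusted p = 0.000981 with an estimated correlation). Of the 4 apical plate and neuronal features, 3 fell: ANKAT-1.1.2 (-2.35), ANKAT-1.2.2 (-2.03) and NK2.1 (-1.29) (3 lower and 1 higher adjusted over the list alone, list adjusted p = 0.0168, adjusted p = 0.151 with an estimated correlation and 0.0802 without set F3). Of the 14 matrix and secreted protease features, 3 rose, MMP16 and the blastula protease features BP10.3.6 (1.5 ± 0.38) and BP10.2.6 (2.36), and 4 did so adjusted over the list alone (list adjusted p = 0.0055, adjusted p = 0.476 with an estimated correlation). In the skeleton list of 14, the spicule matrix features SM30A.1.2 and SM30A.2.2 changed by -0.84 and -0.63 while PM27 rose by 0.34 (4 higher and 3 lower adjusted over the list alone). That list had no single direction (adjusted p = 0.675, median 0.19, mean -0.021), but its members changed in either direction (fry mixed adjusted p = 5.72e-07). None of the 13 ribosomal protein or 20 oxidative phosphorylation features was called over all features or adjusted over the list alone. Small positive shifts gave both lists a camera call (medians 0.14 and 0.080, adjusted p = 0.0055 and 0.0141), which ended with an estimated correlation (adjusted p = 0.63 for both). Without set F1 the protease, ribosomal protein and oxidative phosphorylation calls ended (medians 0.159, 0.103 and 0.0337, adjusted p = 0.219, 0.168 and 0.219). UNIV, a TGF-beta family ligand, rose by 0.35 in the ectoderm list (1 higher and 1 lower of 4, 1 and 2 adjusted over the list alone, list adjusted p = 0.268).

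The remaining lists did not pass camera with ZnO: heat shock, xenobiotic, endoderm, cilia and apoptosis each had an adjusted p of 0.919, early blastula 0.244 (2 of 8 higher, both BP10, and 2 adjusted over the list alone) and late stage 0.268 (0 of 4, and 1 lower adjusted over the list alone). No heat shock, endoderm, cilia or apoptosis member was called over all features or adjusted over the list alone, and the xenobiotic list had 0 over all features and 2 higher and 1 lower adjusted over the list alone. By fry's mixed test, xenobiotic members also changed in either direction (adjusted p = 6.03e-05), as did the protease members (7.59e-10) and the metallothionein members (4.88e-10), and no other list passed it besides skeleton. Without set F1 the endoderm median was 0.23 (adjusted p = 0.0454), against -0.10 with all sets. Median and test differed in sign for heat shock (0.075, lower by camera, mean 0.013), xenobiotic (-0.13, higher by camera, mean 0.098) and apoptosis (-0.021, higher by camera, mean 0.11). The 3 iron features FECH, HEMH and MYP differed by -0.11 to 0.032 (list adjusted p = 0.967, median -0.013, mean -0.029, higher by camera). Lists with fewer than 3 members had no set test, and neither antioxidant feature (GPX1 and SODC), neither cell cycle feature (CCNE and CYCA), nor the complement feature C3 of the pigment and immune list was called. No feature matched the muscle list.

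In all, 1311 of 62865 features (2.09%) were called with ZnO, 596 higher and 715 lower, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The count was 651 without the F1 ZnO library, 873 without the F3 control and 30 without the set term. Of the 50 named features called, 32 kept their call without any 1 library and 18 lost it. MT.15.23, UNIV, EH2, BP10.3.6, BP10.2.6, ANKAT-1.1.2, ANKAT-1.2.2 and PM27 were no longer called without the F1 ZnO library (adjusted p = 0.228, 0.215, 0.144, 0.397, 0.229, 0.151, 0.456 and 0.186), and NK2.1 and SM30A.2.2 without the F3 ZnO library (adjusted p = 0.202 and 0.289). The same held without F1 ZnO for EGIP, ACT1.1.2, ACT2, BMP1, ERG.1.2 and FREM2 (adjusted p = 0.29, 0.534, 0.299, 0.144, 0.126 and 0.343), for NADK.1.3 without F3 ZnO (0.243) and for DUOX1.1.2 without F2 ZnO (0.0538).

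**Figure D2:**
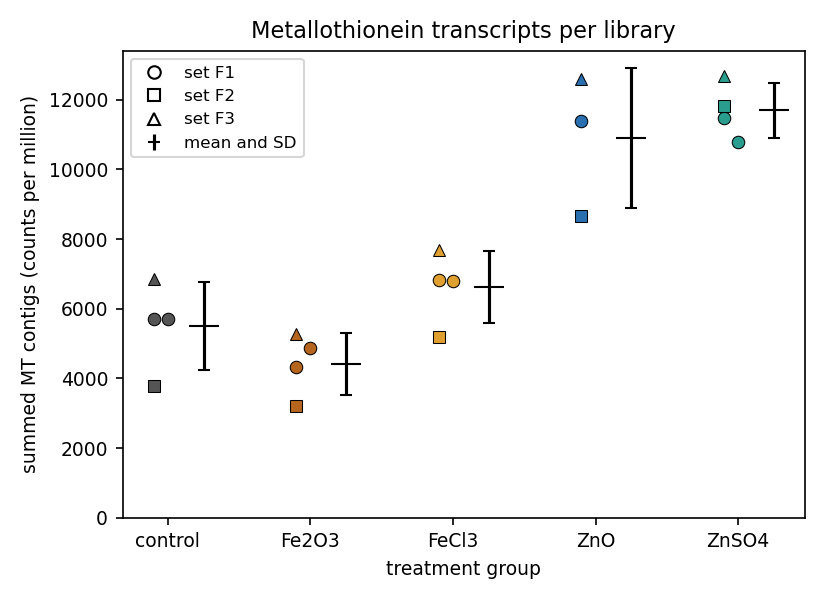
Summed CPM of the 23 metallothionein features in each library (points) by treatment, with the mean and SD of each treatment. ZnO (10900 ± 2020 CPM, n = 3) and ZnSO4 (11700 ± 789 CPM, n = 4) lie above the controls (5510 ± 1270 CPM, n = 4), while FeCl3 (6620 ± 1040 CPM, n = 4) and Fe2O3 (4420 ± 896 CPM, n = 4) lie nearer to them.

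Dissolved zinc, given as ZnSO4, changed many of the same transcripts. All 23 metallothionein features rose, from 0.91 for MT.11.23 to 4.76 ± 0.21 for MT.19.23 (SE, adjusted p = 2.35e-13), and their sum reached 11700 ± 789 CPM (SD, n = 4), a log2 rise of 1.12 ± 0.08 (SE, adjusted p = 4.46e-09). S39AE, a member of the ZIP family of metal transporters, fell by 0.42 (adjusted p = 0.0032). HMB1, DLX and ACAC.1.3 changed by -2.98, -1.94 and -1.48, and MMP16 and ACTG1 rose by 1.40 ± 0.10 (adjusted p = 4.08e-09) and 0.96 ± 0.12 (adjusted p = 1.7e-05). CHRD, the chordin gene, whose product antagonizes BMP signalling, fell by 3.20 ± 0.56 (SE, adjusted p = 0.000633), from 277 ± 33.6 to 38.3 ± 39.1 CPM (SD).

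Heat shock features rose in the ZnSO4 comparison. Of the 7 members, 5 were higher both over all features and adjusted over the list alone, led by HSP74.1.2 (2.99 ± 0.57, adjusted p = 0.00148) and HSP74.2.2 (1.76 ± 0.32, adjusted p = 0.000925), both of the Hsp70 chaperone family. The list passed (adjusted p = 0.0201, adjusted p = 0.381 with an estimated correlation). The change of HSP74.2.2 differed between sets (adjusted p = 1.03e-05), at 2.48 in F1, 0.44 in F2 and 0.10 in F3. Without set F1 the list median was -0.021 (adjusted p = 0.838, and 0.143 with the F1 libraries summed), and HSP74.1.2 and HSP72.2.3 stood at -0.0999 and -0.0671. HSP72.1.3 and HSP72.2.3, also called, lost their calls without 1 library (highest adjusted p = 0.152 without F1 ZnSO4 replicate 2 and 0.165 without F1 control replicate 1).

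Of the 4 ectoderm patterning features, 3 fell with ZnSO4 and 1 rose. CHRD, DLX and the homeobox gene HMX (-1.24 ± 0.24, adjusted p = 0.00162) were lower and UNIV was higher (0.38 ± 0.07), and the same were called adjusted over the list alone (list adjusted p = 0.0201, adjusted p = 0.302 with an estimated correlation). The list call ended without set F1 (median -1.26, adjusted p = 0.146) and with the F1 libraries summed (adjusted p = 0.0683). Of the 6 endoderm and gut features, the homeobox gene EVE fell by 0.59 (adjusted p = 0.0015), and 5 were lower adjusted over the list alone (list adjusted p = 0.000288, median -0.62, adjusted p = 0.302 with an estimated correlation). Without set F1 the endoderm median was 0.0652 and the late stage median 0.0614 (adjusted p = 0.637 for both). The late stage list of 4 was lower (median -0.62, adjusted p = 0.00201, adjusted p = 0.204 with an estimated correlation), with the spicule matrix gene SM30 called (-0.595) and all 4 lower adjusted over the list alone. Its other 3 members, features of the gut marker ENDO16, also belong to the endoderm list. In the skeleton list, SM30, SM29, SM30A.1.2 and SM30A.2.2 changed by -0.595, -0.24, -0.86 and -0.57, and 2 features of FGFRL1, an FGF receptor-like gene, rose by 0.53 and 0.44 (6 higher and 4 lower adjusted over the list alone). As with ZnO, the skeleton list had no single direction (adjusted p = 0.904, median 0.17, mean -0.070, fry mixed adjusted p = 3.16e-11). The Wnt ligand gene WNT2 rose by 0.74, the calmodulin gene CALM3 by 0.45 and ZN782 by 0.55, while FREM2, an extracellular matrix gene, fell by 0.92 and the alpha-tubulin feature TBA1.3.12 changed by -1.01.

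The metallothionein and zinc transport list passed with ZnSO4, with 23 higher and 1 lower, the same adjusted over the list alone (median 1.08, adjusted p = 1.49e-52, adjusted p = 0.00142 with an estimated correlation). Matrix and secreted proteases had 3 of 14 higher, as adjusted over the list alone (MMP16, BP10.2.6 by 2.56 and BP10.3.6 by 1.54, list adjusted p = 0.0478, adjusted p = 0.49 with an estimated correlation, and 0.0961 and 0.123 without sets F2 and F3). Ribosomal proteins had none of 13 called and a median of 0.13 (adjusted p = 0.0241, adjusted p = 0.683 with an estimated correlation), and a median of 0.0426 without set F2 (adjusted p = 0.766). The remaining lists did not pass camera, with adjusted p-values of 0.118 for the apical and neuronal list, 0.869 for xenobiotic, 0.847 for cilia and for apoptosis, 0.236 for oxidative phosphorylation, 0.607 for early blastula and 0.479 for iron. Without set F1 the apical list (median -1.43, adjusted p = 0.0198) and the early blastula list (0.921, adjusted p = 0.0225) passed. Among the xenobiotic members, 2 features of ABCB4, an ABC transporter, changed by 1.38 (ABCB4.7.7) and -0.60 (ABCB4.4.7). Among the oxidative phosphorylation members, NDUFS7, a subunit of respiratory complex I, fell by 0.52. NDUS7, another spelling of that name, was not called. The median and mean differed in sign for xenobiotic (-0.054 and 0.089), cilia (0.019 and -0.018) and apoptosis (-0.0066 and 0.086). Counts over all features and adjusted over the list alone were 1 higher and 1 lower against 1 and 3 for xenobiotic, 1 lower in both for oxidative phosphorylation, and 2 higher and 1 lower against 2 and 2 for early blastula. These 3 lists passed fry's mixed test for changes in either direction (adjusted p = 1.67e-05 for xenobiotic and 0.0322 for the others), as did the protease (1.9e-11), metallothionein (3.16e-11) and skeleton lists, and no other list did. The apical, cilia, apoptosis and iron lists had none in either. C3 differed by 0.38 (adjusted p = 0.0581, 1 higher adjusted over the list alone), the antioxidant features by 0.043 to 0.13 and the cell cycle features by 0.020 to 0.10, with none called over all features.

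ZnSO4 gave 3405 called features (5.42%), 1477 higher and 1928 lower. Without the set term the count was 116, with the F1 libraries summed 1707, and without set F1 1981. Of the 57 named features called, 48 kept their call without any 1 library. Among the others, ZN782 had an adjusted p of up to 0.12 without F1 control replicate 2, FGFRL1.1.2 of 0.0522 without F1 ZnSO4 replicate 2, SM30A.2.2 of 0.0965 without F1 control replicate 2 and ABCB4.7.7 of 0.0898 without the F3 control. BP10.2.6 had a mean log2 CPM of -0.425 and ABCB4.7.7 of -0.058, below the floor for the genes named by size of change, and both are given as list members.

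ZnO and ZnSO4 shared 460 higher and 599 lower features, with 0 in opposite directions. Independent lists of these sizes would share 14 higher and 21.9 lower features. Their log2 changes correlated at 0.673 across features (which are not independent replicates), against a simulated mean of 0.463 from the shared controls alone and 0.349 with split controls. The covariance was 0.0809 against 0.0239 simulated, a difference of 0.0571. For pairs that include an iron treatment, the correlations were 0.512 for Fe2O3 and FeCl3 (simulated 0.505), 0.318 for Fe2O3 and ZnO (0.460), 0.293 for Fe2O3 and ZnSO4 (0.503), 0.389 for FeCl3 and ZnO (0.464) and 0.365 for FeCl3 and ZnSO4 (0.509). Their covariances differed from the simulated ones by 0.00325, 0.000215, 0.000154, 0.00638 and 0.00685, and with split controls these correlations lay between -0.0452 and 0.0161.

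**Figure D3:**
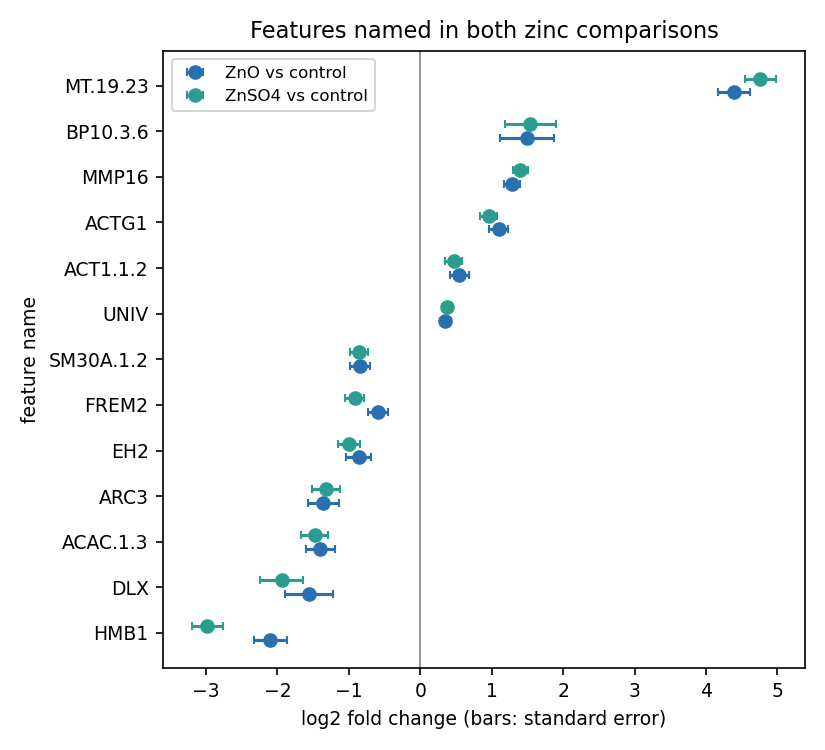
Log2 fold change against control, with SE, of 13 features named in both zinc comparisons, for ZnO and ZnSO4. Each feature has the same sign in both, from HMB1 (-2.10 and -2.98) to MT.19.23 (4.39 and 4.76).

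Compared directly, the zinc particle and the zinc salt differed in 49 features, 28 higher and 21 lower with ZnO. TRIM25, a ubiquitin ligase, was higher by 0.97 ± 0.19 (adjusted p = 0.0408), EVE by 0.67 ± 0.12 (adjusted p = 0.0267) and NDUFS7 by 0.66 ± 0.12 (adjusted p = 0.0383). NDUS7, another spelling of NDUFS7, was not called. ANKAT-1.2.2 was lower (log2 difference -2.17 ± 0.41, adjusted p = 0.0366), with set values of -2.74, -0.46 and 3.08, so its direction was not shared by the sets. Summed metallothionein did not pass the test (log2 difference -0.12 ± 0.09, adjusted p = 0.891). Heat shock features lay lower with ZnO than with ZnSO4 (median -0.32, 0 called over all features and 5 lower adjusted over the list alone, adjusted p = 0.000408), and endoderm features higher (median 0.52, 1 called, EVE, also adjusted over the list alone, adjusted p = 2.77e-05). The late stage list was also higher (median 0.52, adjusted p = 0.0217) and the metallothionein list lower (median -0.13, adjusted p = 0.00249), with 0 called in either over all features. With an estimated correlation the adjusted p-values were 0.367 for the first 3 of these lists and 0.553 for metallothionein. Without set F1 the heat shock, endoderm and late stage calls ended (medians -0.0827, 0.165 and 0.165, adjusted p = 0.244, 0.204 and 0.316), the metallothionein median was -0.261 and ribosomal proteins lay lower (-0.131, adjusted p = 0.0175). Without set F2 the metallothionein list had a median of 0.0172 and an adjusted p of 0.8, and in that set its features summed to 8652 CPM with ZnO and 11810 with ZnSO4. Ectoderm, protease, oxidative phosphorylation, ribosomal protein and skeleton lists also passed without F2 (adjusted p = 0.0449, 0.0127, 0.00875, 0.00854 and 0.00854). The late stage call also ended with the F1 libraries summed (adjusted p = 0.14). Adjusted over the list alone, 1 metallothionein list member was lower, 0 late stage members were called, and the apical list had 1 higher and 3 lower (list adjusted p = 0.354). Median and mean differed in sign for apoptosis (-0.035 and 0.027) and early blastula (-0.020 and 0.10), neither of which passed.

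The number of features that differed between ZnO and ZnSO4 depended on single libraries. It was 4 without the F3 ZnO library, 26 without F2 ZnO, 342 without F1 ZnO, 14 and 22 without F1 ZnSO4 replicate 1 and 2, 378 without F2 ZnSO4 and 426 without F3 ZnSO4. None of the 4 named features kept its call without every library: the highest adjusted p was 0.322 for TRIM25 (without F2 ZnO), 0.186 for EVE and 0.256 for NDUFS7 (without F3 ZnO), and 0.425 for ANKAT-1.2.2 (without F1 ZnO).

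In embryos exposed to FeCl3, 5 metallothionein features rose. MT.2.23 rose by 1.3 ± 0.15 on the log2 scale (adjusted p = 9.07e-05), MT.17.23 by 1.18 ± 0.12 (adjusted p = 7.27e-05), MT.19.23 by 1.46 ± 0.25 (adjusted p = 0.022), MT.23.23 by 1.45 ± 0.24 (adjusted p = 0.0125) and MT.7.23 by 0.46 ± 0.08 (adjusted p = 0.0418). In CPM, MT.2.23 stood at 3.61 ± 0.83 in controls and 8.93 ± 2.39 with FeCl3 (SD, n = 4 each), against 41.7 ± 19.6 with ZnO and 60 ± 24.5 with ZnSO4. Adjusted over the list alone, 15 of the 24 list members were higher (median 0.24, adjusted p = 2.12e-17, adjusted p = 0.102 with an estimated correlation, fry adjusted p = 0.0203). The summed features, at 6620 ± 1040 CPM, did not pass the test (log2 difference 0.28 ± 0.08, unadjusted p = 0.00281, adjusted p = 0.999). None of the iron features was called, with log2 differences of -0.0063 for FECH (ferrochelatase), 0.018 for HEMH and -0.49 for MYP (the major yolk protein), and a list adjusted p of 0.665. FECH and HEMH both name ferrochelatase, and no other member was measured, so the list covers little of iron homeostasis.

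FeCl3 gave 17 called features, 15 higher and 2 lower. At an unadjusted p under 0.05 there were 2751, fewer than the 0.05 of 62865 tested features that chance alone would give. Besides the metallothionein features, 10 numbered contigs rose, the largest changes being 2.02 for contig_20334 and 1.95 for contig_10271, and LOC577189.1.2 and LOC592902 changed by -1.63 and -0.58. The files do not pair these with gene names. All 15 were also higher and both others lower in the ZnO and the ZnSO4 comparison, where independent lists would share 0.142 and 0.0227 features (ZnO) and 0.352 and 0.0613 (ZnSO4). Part of this overlap may come from the controls, which the comparisons share. Matrix and secreted proteases lay lower (median -0.22, 0 of 14 called, also adjusted over the list alone, adjusted p = 0.0403, adjusted p = 0.855 with an estimated correlation), and no other list passed. The protease call ended without set F3 (adjusted p = 0.23), with the F1 libraries summed (0.0659) and without the set term (0.108), and the skeleton list passed without set F2 (median -0.0926, adjusted p = 0.0252). Median and mean differed in sign for xenobiotic (-0.023 and 0.034) and early blastula (-0.013 and 0.013), and the apical list had a median of 0.017 where the test pointed lower. The count was 11 without F1 control replicate 1, 11 without F1 FeCl3 replicate 1, 87 with a fit to only the groups compared and 0 without the set term (170 unadjusted). MT.2.23 and MT.17.23 kept their calls without any 1 library, while MT.19.23, MT.23.23 and MT.7.23 did not (highest adjusted p = 0.399 without F3 FeCl3, 0.126 without F1 control replicate 2 and 0.449 without the F2 control).

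With Fe2O3 particles, all 24 members of the metallothionein and zinc transport list had log2 differences below 0 (median -0.32), but none was called over all features. Adjusted over the list alone, 19 were lower (list adjusted p = 1.09e-24, adjusted p = 0.0316 with an estimated correlation, fry adjusted p = 0.0142). Summed metallothionein stood at 4420 ± 896 CPM against 5510 ± 1270 in controls (SD, n = 4 each), a log2 difference of -0.31 ± 0.08 that did not pass over all features (unadjusted p = 0.000938, adjusted p = 1). FECH, HEMH and MYP differed by -0.054, -0.015 and -0.12, and the iron list had an adjusted p of 0.76. The other lists tested had adjusted p-values of at least 0.76, and the median lay above 0 for matrix and secreted proteases (0.025, mean 0.20) where the test pointed lower. For apoptosis the median was -0.040, the mean 0.096 and the test direction higher.

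No feature was called with Fe2O3 by the edgeR quasi-likelihood test (1821 at an unadjusted p under 0.05), and 0 by DESeq2 (1576 unadjusted). Both unadjusted counts lie below the 0.05 of 62865 tested features that chance alone would give. A fit to only the control and Fe2O3 libraries called 24, and leaving out the F3 Fe2O3 library called 1. On simulated counts the same test recovered 62.7% of 2-fold changes and 35.8% of 1.5-fold changes, so smaller differences were not reliably detectable with these libraries.

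Libraries of the iron particle and the iron salt differed in metallothionein. Zinc-library reads in the FeCl3 libraries, left open below for FeCl3 against control, were not tested for this contrast. With Fe2O3, 16 of the 23 metallothionein features were lower than with FeCl3, from -0.49 for MT.13.23 to -2.08 ± 0.16 for MT.2.23 (adjusted p = 5.32e-08), and MT.17.23, MT.19.23 and MT.23.23 differed by -1.91, -1.82 and -1.80. Their sum differed by -0.59 ± 0.08 (adjusted p = 0.00192). Adjusted over the list alone, 22 of 24 were lower (median -0.58, adjusted p = 2.24e-58, adjusted p = 0.000876 with an estimated correlation). Matrix and secreted proteases lay higher with Fe2O3 (median 0.27, 0 of 14 called, also adjusted over the list alone, adjusted p = 0.024, adjusted p = 0.862 with an estimated correlation, 0.307 without set F1 and 0.141 with the F1 libraries summed). No other list passed, and median and mean differed in sign for iron (-0.033 and 0.098), apoptosis (-0.0028 and 0.18) and oxidative phosphorylation (-0.0014 and 0.0050).

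In all, 46 features differed between Fe2O3 and FeCl3, 2 higher and 44 lower with the particle. Both higher ones, LOC577189.1.2 (1.10) and LOC587958.3.3 (0.97), were lower in both zinc comparisons, and all 44 lower ones, of which contig_33629 differed most (-3.07), were higher in both. Independent lists would share 0.019 and 0.5 such features with ZnO and 0.047 and 1.35 with ZnSO4. Zinc-library reads in the FeCl3 libraries could also give such an overlap. Without F1 Fe2O3 replicate 1 the count was 27, without F3 Fe2O3 30, without F3 FeCl3 28, with only the groups compared 78, and without the set term 0 (138 unadjusted). Of the 16 metallothionein calls, 10 held without any 1 library, and MT.13.23 reached an adjusted p of 0.352 without F1 Fe2O3 replicate 1.

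Both zinc treatments together differed from both iron treatments in 4690 features (7.46%), 2116 higher and 2574 lower, a contrast that uses no control library. Metallothionein members rose in 23 of 24 cases and 1 fell, the same adjusted over the list alone (median 1.12, adjusted p = 0.00088 with an estimated correlation). In the skeleton list, 8 of 14 features were higher and 3 lower, the same adjusted over the list alone: SM37.1.2 (0.26), SM41.2.3 (0.30) and PM27 (0.34) rose while SM30A.1.2 (-0.89) and SM30 (-0.51) fell, and the list had no single direction (adjusted p = 0.115, fry mixed adjusted p = 5.12e-12). Of the 14 protease features, 7 were higher, also adjusted over the list alone, among them MMP16 (1.27), MMP14.2.5 (0.63) and BP10.2.6 (1.83) (list adjusted p = 8.49e-05, adjusted p = 0.157 with an estimated correlation). Complement C3 rose by 0.39. Heat shock features (5 of 7 higher, 5 higher and 1 lower adjusted over the list alone) had a list adjusted p of 0.0252, ectoderm features (1 higher and 3 lower of 4, the same adjusted over the list alone) 0.0378 and apical features (3 lower of 4, 1 higher and 3 lower adjusted over the list alone) 0.0218. With an estimated correlation these were adjusted p = 0.345, 0.323 and 0.157. Endoderm features lay lower (median -0.3, 0 of 6 called, also adjusted over the list alone, adjusted p = 0.0252, adjusted p = 0.453 with an estimated correlation), as did the late stage list (median -0.309, SM30 of 4 called, also adjusted over the list alone, adjusted p = 0.0184, adjusted p = 0.282 with an estimated correlation). Oxidative phosphorylation lay higher (median 0.0926, NU6M of 20 called at 0.263, also adjusted over the list alone, adjusted p = 0.00575, adjusted p = 0.345 with an estimated correlation). The xenobiotic list did not pass camera (adjusted p = 0.972, median -0.0407, mean 0.041), nor did early blastula (0.206), but both passed fry's mixed test (adjusted p = 0.000353 and 0.0182). Ribosomal proteins had 0 of 13 called over all features and 13 higher adjusted over the list alone (median 0.14, adjusted p = 0.000126, adjusted p = 0.345 with an estimated correlation). Of the 4690 features, 780 had an estimated log2 difference above 1 in size, and the fit without the set term called 334.

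Zinc effects differed between the sets by a set-by-treatment test, in which F2 and F3 have 1 library per treatment, as ZnO has in F1, and these are assumed to vary like the F1 pairs. The test called 890 features for ZnO, 2356 for ZnSO4 and 1552 for ZnO against ZnSO4, compared with 1 for Fe2O3, 0 for FeCl3 (2396 at an unadjusted p under 0.05 by the edgeR quasi-likelihood test, with no other tool run) and 1 for Fe2O3 against FeCl3. CHRD changed with ZnSO4 by -5.95 in F1, -1.54 in F2 and -2.12 in F3, and HMB1 with ZnO by -3.30, -1.49 and -1.78. Within the sets, 2919, 676 and 1002 features were called for ZnO in F1, F2 and F3, 5539, 1584 and 1607 for ZnSO4, 0, 0 and 1 for Fe2O3, and 53, 9 and 9 for FeCl3. The F2 and F3 counts, and the ZnO count in F1, compare with a treatment of 1 library, with no replicate check of their own. F1 holds more libraries than the other sets, which can raise its counts. How much of its excess comes from this, and how much from larger effects in F1, was not tested.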

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

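The tests of zinc-library reads, of reads moved between metallothionein features and of the F1 spread were chosen only after the results they bear on were seen, as were the splits within sets and the scale of the check for single libraries far from the rest of their treatment.

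With FeCl3, 5 metallothionein features rose. Reads moved between near-identical features leave their sum as it was, but the sum differed by 0.277 (95% interval 0.105 to 0.448 for this single test) and the other metallothionein features together by 0.271 (0.0424 to 0.5), which argues against such moves as the whole of it. For the excess of the 5 called features such moves stay open, because the 117 CPM these gained would change the others by only -0.0326 on the log2 scale, less than the half-width of 0.229 of that interval. A share of reads from zinc libraries, tested in 8 settings per size class, stays open beside a response to the salt, because other features higher by over 2 with zinc had medians of 0.392 to 0.987 against predicted medians of 0.346 to 1.5 (highest difference 0.0479, intervals below 0 in 3 settings and spanning 0 in 5). Against it, features higher by 1 to 2 stayed below the prediction in all 8 (differences -0.369 to -0.0994). Features lower by 1 to 2 and by over 2 lay above the prediction in 5 and 6 of 8, with intervals that span 0 in the rest. The pooled test gave differences of -0.147 and -0.522 with either part of the controls. It decides nothing here, because choosing and sizing features by the same contrast favours a shortfall.

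With Fe2O3, the metallothionein list lay lower than in controls. Reads moved between near-identical features would not lower the sum, whose 95% interval was -0.485 to -0.143, and no single library carried the difference, since the list median nearest 0 was -0.296, without the F2 Fe2O3 library. Features higher by over 2 with zinc lay above what zinc-library reads in the controls predict in all 8 settings (differences 0.167 to 2.08). This argues against such reads as the whole of the difference. Features higher by 1 to 2 lay above the prediction in 6 of 8 settings, with intervals that span 0 in 2 (lowest difference -0.0159). In those 2, features higher by over 2 lay above it by 0.213 and 0.493. Intervals also spanned 0 for features lower by 1 to 2 in 2 settings and lower by over 2 in 3, so such reads stay open as a part of it. Features lower by 1 to 2 and by over 2 lay below the prediction in 6 and 5. The pooled test gave 0.498 and 0.268, and decides nothing for the same reason as with FeCl3. A lowering by the particle remains a hypothesis, and its size could not be set apart from a smaller part due to zinc-library reads in the controls.

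Zinc effects differed between the sets for 890 features with ZnO, 2356 with ZnSO4 and 1552 between ZnO and ZnSO4. A spread of the F1 pairs too small for the other sets could give such counts, but it would also apply to the iron treatments, where at most 1 feature differed (1 for Fe2O3, 1 for Fe2O3 against FeCl3), which argues against it. The F2 and F3 libraries are single, so a larger spread of the zinc libraries alone stays open. What the sets are is not given in the sources used here, so parents, batch and day cannot be told apart, and a biological difference between the sets stays open and untested.

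Among the named genes, the test of the difference between sets gave adjusted p-values with ZnO of 0.0284 for ACTG1, 1.85e-08 for HMB1, 1.12e-09 for DLX, 0.00462 for ARC3, 0.0023 for NK2.1 and 8.3e-05 for FREM2. With ZnSO4 they were 1.03e-05 for HSP74.2.2, 0.00464 for WNT2, 0.0238 for FGFRL1.1.2, 0.00105 for DYNLRB2, 6.27e-17 for CHRD, 0.00042 for HMB1 and 2.73e-05 for DLX. They were 7.9e-05 for ACAC.1.3, 0.00204 for ARC3, 1.12e-06 for HMX, 3.5e-08 for ARS.3.5, 0.00425 for EH2 and 0.00107 for FREM2. ARS.3.5, an arylsulfatase feature, changed by -0.56, -2.98 and -0.14 in F1, F2 and F3.

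In 8 of 160 groups of libraries, 1 library stood far from the others of its treatment in log2 CPM minus the set mean, where chance gives about 1 in 20. The F2 control stood at -0.613 for summed metallothionein and at 0.75 for HMB1. F1 control replicate 2 stood at 0.168 for ACT2 and F1 control replicate 1 at 0.392 for ARC3. The F3 Fe2O3 library stood at -1.96 for BP10.3.6, F1 FeCl3 replicate 2 at -0.575 for ACTG1 and -0.403 for ACT2, and the F2 ZnSO4 library at -2.18 for ARS.3.5.

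Other splits of the same libraries were refitted for each count. Over all 35 splits none but the real one gave as many calls for FeCl3 (17 features, highest other 0, 1 of 35 splits as large, the real one included), ZnO (1311, highest other 168), ZnSO4 (3405, highest other 148) and Fe2O3 against FeCl3 (46, highest other 1). Only 12 of the 35 keep the number of libraries per set, which is too few for a share under 0.05, with the highest other among them at 0, 57, 63 and 0. For zinc against iron no other split gave as many calls (4690, 1 of 100 splits, the real one included, highest other 3337, and 2542 in 100 splits within sets). With splits within treatments the same held for F2 against F1 (44327, highest other 24804, and 31768 over all splits) and F3 against F1 (43658, highest other 24080, and 29178). All these splits treat the libraries as separate units, which the labels do not establish. For F3 against F2 (40359, highest other 19932 over 100 splits) the 16 splits within treatments are too few for a share under 0.05 (highest other 1). For Fe2O3 the splits decide nothing, because with 0 features called (edgeR quasi-likelihood test and DESeq2, 1821 and 1576 unadjusted) all 35 of 35 splits give as many (highest other 1). For ZnO against ZnSO4, 12 of 35 splits gave as many calls (49, highest other 2289, and 188 within sets), and splits with many calls point to a structure of the samples. The split with 2289 calls follows the set, with the 3 zinc libraries of F1 against those of F2 and F3.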

How the results depend on the processing

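Summing the features of 1 name was chosen after the data were seen; all other alternatives were planned. Under them 168 counts stayed within 1.5 times their value, 60 moved beyond it, 6 fell to 0 and 2 rose from 0. Of the list results 680 kept the direction of the test (not compared for fry) and the side of the threshold, 60 were no longer called, 13 became called, 4 reversed, and 53, called in neither, changed direction. Of the named-gene results 8451 kept both, 438 were no longer called, 104 became called, 2 reversed, and 440, called in neither, changed sign. The cause was not tested, except that a bar on the size of the estimated change can only lower a count. Leaving out libraries lowered some counts and raised others, as for ZnO against ZnSO4 (49 with all libraries, 4 to 426 without 1).

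A bar of 1 on the size of the estimated log2 change left 450 called features for ZnO and 880 for ZnSO4. It left 26 for Fe2O3 against FeCl3, 9 for ZnO against ZnSO4 and 780 for zinc against iron. For the sets it left 19651 for F2 against F1, 19323 for F3 against F1 and 17824 for F3 against F2. No test was made against that bar. DESeq2 gave 191 for ZnO against ZnSO4. Without the set term, edgeR called 0 for FeCl3, Fe2O3 against FeCl3 and ZnO against ZnSO4 (170, 138 and 448 unadjusted), 30 for ZnO, 116 for ZnSO4 and 334 for zinc against iron, and the ZnO and ZnSO4 changes correlated at 0.567. List calls then ended for oxidative phosphorylation with ZnO (adjusted p = 0.188) and metallothionein in ZnO against ZnSO4 (0.0628), and appeared for ectoderm with ZnO (0.0132) and in ZnO against ZnSO4 (0.00195), apical with ZnSO4 (0.0231) and skeleton with FeCl3 (0.0442). With the F1 libraries of a treatment summed, counts were 9 for FeCl3, 837 for ZnO, 1707 for ZnSO4, 27 for Fe2O3 against FeCl3 and 1 for ZnO against ZnSO4, and 1 list passed for Fe2O3 against FeCl3 and 1 for FeCl3. With features of 1 name summed, they were 11 for FeCl3 and 26 for Fe2O3 against FeCl3. With only the groups compared, they were 24 for Fe2O3, 87 for FeCl3, 78 for Fe2O3 against FeCl3 and 99 for ZnO against ZnSO4.

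Deviations of same-numbered F1 libraries from their treatment means did not correlate (-0.0723 to 0.0495). Their 12 pairs are not 12 separate values, because the deviations of 2 replicates mirror each other. An effect of the replicate number stays open. Chi-square per degree of freedom was 3.26 for control and Fe2O3 replicates 1 and 4.407 for their replicates 2, against 5.481 and 7.929 within the treatments. Control and FeCl3 were mixed, with 3.81 between replicates 1, against 5.481 and 4.163 within the treatments. Their replicates 2 gave 8.634, against 7.973 between control replicate 2 and FeCl3 replicate 1. With the replicate number as a block, which left out the F1 ZnO library, the counts were 574 for ZnO and 277 for ZnO against ZnSO4, and 1 list passed for FeCl3 and 1 for ZnO.

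Without set F1, 1981 features were called for ZnSO4, 29 for Fe2O3 against FeCl3, 300 for ZnO against ZnSO4 and 2692 for zinc against iron, and 1, 3 and 2 lists passed for Fe2O3 against FeCl3, ZnO and ZnO against ZnSO4. The direction of camera's test reversed, with a call in either fit, for endoderm with ZnO (median 0.23, adjusted p = 0.0454) and ZnSO4 (0.0652). It also did so for heat shock with ZnSO4 (-0.021) and ribosomal proteins in ZnO against ZnSO4 (-0.131, adjusted p = 0.0175). Other medians changed sign too, among them late stage with ZnO (0.242) and ZnSO4 (0.0614). HSP74.1.2 (-0.0999) and HSP72.2.3 (-0.0671) reversed with ZnSO4. Without set F2, 8 lists passed for ZnO against ZnSO4. Without set F3, counts were 25 for Fe2O3 against FeCl3 and 83 for ZnO against ZnSO4, and 1 list passed for FeCl3. With an estimated correlation 1 list passed for Fe2O3 against FeCl3, ZnO and ZnSO4 each and 0 for FeCl3 and ZnO against ZnSO4. With fry, 1 passed for Fe2O3 against FeCl3, 1 for FeCl3, 2 for ZnO, 3 for ZnSO4 and 0 for ZnO against ZnSO4.

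Split controls gave correlations of -0.0213 for Fe2O3 and FeCl3, -0.0452 for Fe2O3 and ZnO, -0.0429 for Fe2O3 and ZnSO4, 0.0126 for FeCl3 and ZnO, 0.0161 for FeCl3 and ZnSO4 and 0.349 for ZnO and ZnSO4. Leaving out each library gave 0 to 1 for Fe2O3 (1 without F3 Fe2O3), 11 to 15 for FeCl3, 651 (without F1 ZnO) to 1381 for ZnO, 2288 to 4046 for ZnSO4, 27 to 39 for Fe2O3 against FeCl3, 4 (without F3 ZnO) to 426 (without F3 ZnSO4) for ZnO against ZnSO4 and 3521 to 5268 for zinc against iron. Library totals ran from 24438369 to 32801015 counts, and the effect of depth on the calls was not tested.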

Other observations

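These values were computed after the results against control had been seen. The iron treatments were also read on the features that responded most to zinc, with zinc calls from one part of the controls and iron changes from the other. Metallothionein features and features called with FeCl3 were not taken out, so part of this repeats the FeCl3 calls. Over the 39 and 43 features that rose by more than 2 on the log2 scale in zinc, the median change with FeCl3 was 1.06 and 0.852, and 87.2% and 86% of them lay above 0. For Fe2O3 the medians were -0.337 and -0.336, with 7.69% and 18.6% above 0. Over the 142 and 148 features that rose by 1 to 2, the medians were 0.0344 and -0.0485 with FeCl3 and -0.0781 and -0.0967 with Fe2O3. Features that fell by more than 2 in zinc (62 and 72) had medians of -0.111 and 0.0103 with FeCl3 and -0.0136 and 0.084 with Fe2O3. Zinc-library reads, left open above for FeCl3, could also give the rises with FeCl3.

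Summed metallothionein lay below the controls with Fe2O3 and above them with FeCl3 in each set. In F2 it stood at 3207 CPM with Fe2O3, 3775 in the control and 5182 with FeCl3, and in F3 at 5275, 6842 and 7679 CPM.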
